A study of Rattus norvegicus with 54 samples.

How the data were processed

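The deposited values were linear intensities, MAS5 signals computed by the authors before deposit from Affymetrix Rat Expression Set 230A arrays, and the submitters' processing notes name MAS5 without a version. The authors pooled RNA from 2 rats for each array, so 3 arrays stand for 6 rats per group. In the deposited values no signal lay below 0 and the mean after trimming the lowest and highest 2% of probe sets was 500 on every array, and no further scaling was applied. Of 15923 probe sets 57 were controls and were left out. Of the other 15866, 12783 had 1 gene symbol, 312 had several and 2771 had none, with 10411 distinct symbols. Entrez identifiers matched 12748 of the probe sets with 1 symbol to the reference gene table, which changed 0 symbols. Probe sets with several symbols or none are called unnamed.

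Signals were used as log2(signal + 20), where 20 is the 10th percentile of all values to 1 digit. In each tissue, probe sets with a mean above the 40th percentile were tested, 9519 in each. Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with trend), with 1 fit per tissue of its 18 arrays and 12 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All p-values for probe sets come from limma. Contrasts were obese minus lean, the mean of the 4 ligand groups minus untreated obese, each ligand minus untreated obese and the 6 differences between ligands, with an F-test over the differences among ligands. Tissue differences in the ligand mean effect were tested by an F-test in a joint fit of all 54 arrays (11520 probe sets), whose calls within a tissue can differ from those of the fit per tissue. Gene lists were tested with camera at a correlation of 0.01 and beside it with an estimated correlation, on the probe set with the highest mean of each gene. At the fixed correlation a drawn split of the arrays gave up to 183 list calls, against 186 for the real groups. List calls at the fixed correlation alone are therefore weak evidence, however small their p-values. The 32 lists were fixed beforehand, and lists with fewer than 5 measured members were not tested. The comparisons, lists, rule for named genes and alternatives were chosen before the data were examined. Exceptions were the alternative that leaves out arrays in doubt, the list tests between tissues and the tests of flagged patterns.

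Named genes followed a rule. They were (a) the 6 largest rises and 6 largest falls among called probe sets with 1 symbol and no overlap between sides, and (b) up to 4 called members of a list by smallest adjusted p. They were also (c) the 8 smallest F-test p-values among ligands and up to 2 per direction in each difference between ligands, (d) the 10 smallest F-test p-values for tissue differences, (e) genes called for all 4 ligands in all 3 tissues, of which there were 0 (limma), and (f) Pparg and Lepr. Srebf1, Cpt1a, Cd36, G0s2, Fads1, Spp1, Gpnmb, Postn, Col6a3 and Col4a1 in some adipose comparisons, Acaca in liver, the other list members given in other observations and the genes named as moving back, moving further or shared between tissues were chosen after their values were seen.

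Alternatives were a pseudocount of 5 or 80, no filter or a filter at the 60th percentile, quantile normalization, median centring, no trend, array weights, the replicate number as a block, fits of only the arrays compared, an adjusted p of 0.01, lists with probe sets averaged, and each array left out in turn. Same-number arrays of different groups had a mean correlation of residuals of 0.0184 in adipose tissue, 0.00322 in liver and 0.0117 in muscle, so numbers were not used as pairs. The pipeline was tested on simulated data with 200 changed probe sets. At a log2 change of 1 it recovered 88% in adipose tissue, 45% in liver and 51% in muscle for obese against lean, and 95, 70 and 78% for the ligand mean. At a change of 2 it recovered 99, 81 and 83%, and 100, 91 and 92%. The share of false calls ran from 1.83 to 7.59%. Shared controls were simulated 100 times, with ligand groups set to the mean of untreated obese rats. Such data hold almost no ligand calls, so their counts of shared or moved-back probe sets are near 0 by construction. Their covariances and correlations show what the shared arrays alone give. Raw image files were not used here.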

Results

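Transcript levels were measured on 54 rat expression arrays that covered 3 tissues of male Zucker rats: epididymal adipose tissue, liver and gastrocnemius muscle. Each tissue had 6 groups of 3 arrays, and each array held a pool of RNA from 2 rats. The groups were lean rats that carry 1 copy of the fa mutation, obese fa/fa rats without a ligand, and obese rats given 1 of 4 ligands of the nuclear receptor PPARgamma. Pioglitazone, rosiglitazone and troglitazone are thiazolidinediones, a class of PPARgamma agonists used to raise insulin sensitivity, and the other ligand is known here only by its code name AG035029. Doses and treatment times are not stated in the labels. The arrays measured 15866 probe sets besides controls, and 9519 of them were tested in each tissue. Median signals per array lay between 205 and 247 in adipose tissue, 201 and 248 in liver and 191 and 232 in muscle. Residual spreads had a median SD of 0.25 on the log2 scale in adipose tissue, 0.40 in liver and 0.39 in muscle, and 3 arrays per group limit the precision. Below, n is 3 arrays for each group and 12 for the mean of the ligand groups, and errors after ± are standard errors on the log2 scale from limma unless an SD is named.

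The comparison of obese with lean rats asks which transcripts the obese state changed before any ligand was given. In adipose tissue the macrophage transcripts Spp1, which encodes osteopontin, and Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, rose by 3.64 ± 0.68 and 3.17 ± 0.29 in log2 (adjusted p = 0.00311 and 4.28e-06). The elastase gene Cela1 rose by 3.47 ± 0.33, from a mean signal of 24.4 in lean rats, under 50, and by 2.40 to 4.02 over the alternatives. The creatine synthesis enzyme Gatm by 2.36 ± 0.23, the amino acid transporter Slc7a10 by 2.36 ± 0.32 and the sodium pump subunit Atp1b1 by 2.23 ± 0.48. The Wnt antagonist Frzb fell by 2.81 ± 0.18, the organic cation transporter Slc22a3 by 2.73 ± 0.20, albumin (Alb) by 2.16 ± 0.37, the adipocyte beta-adrenergic receptor Adrb3 by 2.09 ± 0.43, the glutamate transporter Slc1a3 by 1.97 ± 0.20 and angiotensinogen (Agt) by 1.85 ± 0.41. For Slc1a3, 1 other probe set had a value of 0.36 (adjusted p = 0.146). Leptin (Lep), the hormone whose receptor the fa mutation disables, rose by 1.42 ± 0.32, from a mean signal of 2288 to 6152, and the gene of PPARgamma itself, Pparg, fell by 1.07 ± 0.15.

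Among the fixed gene lists in adipose tissue of obese rats, 9 of 21 macrophage markers rose and 0 fell, with Cd68 at 1.33, Laptm5 at 1.19 and Fcer1g at 0.79, and 13 rose when adjusted over the list alone (list median 0.50, adjusted p = 2.5e-10, and adjusted p = 0.097 with an estimated correlation). Of 15 cholesterol synthesis genes, 5 rose, among them Cyp51 by 1.41 and Dhcr7 by 1.29, and 9 rose when adjusted over the list alone (adjusted p = 7.7e-08, and adjusted p = 0.097 with an estimated correlation). Another Cyp51 probe set had a value of 0.41 that did not pass (limma, adjusted p = 0.344). Of 17 fatty acid synthesis genes, 5 rose, with Elovl6 at 1.49 and Me1 at 1.11, and Srebf1 fell by 0.997 (adjusted p = 0.00107, and adjusted p = 0.303 with an estimated correlation). Of 17 interferon response genes, 7 fell, including Tap1 by 0.83 and Irf9 by 0.61, and 10 fell when adjusted over the list alone (adjusted p = 6.37e-08, and adjusted p = 0.124 with an estimated correlation). Of 18 genes of branched-chain amino acid breakdown, 6 fell, such as Pccb by 0.82 and Bcat2 by 0.53, and 7 when adjusted over the list alone (adjusted p = 0.000688, and adjusted p = 0.174 with an estimated correlation). Of 11 adipocyte markers, 5 fell, with the activin receptor Acvr1c at -1.54, and Lep rose (adjusted p = 0.00361, and adjusted p = 0.303 with an estimated correlation). Of 19 cell cycle genes, 4 rose, such as Cdk1 by 1.09 and Ccnb2 by 1.01 (adjusted p = 0.00021, and adjusted p = 0.097 with an estimated correlation). The lipid droplet coat gene Plin2 rose by 1.68, the cell cycle inhibitor gene Cdkn1a by 1.43, and the secretory pathway regulator Xbp1 fell by 1.16 and the glucocorticoid-responsive factor Klf15 by 1.14. In all, 301 probe sets were higher and 272 lower (limma, adjusted p under 0.05), and the arrays of the groups did not overlap for 569 of these 573. Of all tested probe sets 27.9% had no overlap, where chance gives 10%. Without untreated obese replicate 2 or 3 the total was 365 or 319, and with array weights it was 1106. A filter at the 60th percentile ended the call of the cell cycle list (adjusted p = 0.447). Calls of Tap1, Agpat2 (-0.95) and Fabp3 (1.12) ended without untreated obese replicate 2 and at least 2 other single arrays, with adjusted p up to 0.114, 0.0567 and 0.136. The call of Agt ended without untreated obese replicate 2, untreated obese replicate 3 or lean replicate 1, with adjusted p up to 0.0547.

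The comparison of the mean of the 4 ligand groups with untreated obese rats asks what the ligands had in common. In adipose tissue, Fabp3, a fatty acid carrier of oxidative tissues, rose by 4.82 ± 0.23 in log2, from 405 in untreated obese rats (adjusted p = 3.05e-10), and albumin (Alb) rose by 4.45 ± 0.26. The glycogen synthase isoform Gys2 rose by 2.99 ± 0.22, the matrix protein tenascin C (Tnc) by 2.50 ± 0.33, the secretory granule protein Ptprn by 2.45 ± 0.20 and Cpt1b, which admits fatty acids to mitochondria, by 2.27 ± 0.13. The xenobiotic enzyme Cyp1b1 fell by 2.80 ± 0.20, the secreted phospholipase Pla2g2a by 2.19 ± 0.44, Gatm by 2.11 ± 0.18, the tight junction gene Cldn5 by 2.04 ± 0.12, the tubulin gene Tubb6 by 2.01 ± 0.31 and the chemokine Cxcl12 by 1.85 ± 0.15.

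Genes that burn fuel in mitochondria rose together in adipose tissue under the ligands. Of 24 genes of mitochondrial fatty acid oxidation, 22 rose, among them Cpt1b, Bdh1 by 1.97, Pdk4 by 1.87 and Eci2 by 1.29, and 1 fell, Cpt1a by 0.30 (list median 0.996, adjusted p = 1.33e-23, and adjusted p = 0.00831 with an estimated correlation). Of 54 genes of the citrate cycle and oxidative phosphorylation, 50 rose and 54 rose when adjusted over the list alone, with Sucla2 at 0.90, Atp5f1d at 0.84 and Uqcrfs1 at 0.81 (adjusted p = 4.73e-34, and adjusted p = 0.0276 with an estimated correlation). Of 18 genes of branched-chain amino acid breakdown, 14 rose, with Acadsb at 1.45, Acat1 at 1.12 and Hibch at 0.89, and 7 of 12 peroxisomal genes rose, with Ehhadh at 2.05 and Acot8 at 0.87 (adjusted p = 4.44e-10 and 1.84e-05, and adjusted p = 0.00831 for both with an estimated correlation). Of 23 PPARgamma target genes, 12 rose and 0 fell, and 15 rose when adjusted over the list alone. Cyp4b1 rose by 1.62, Agpat2, which makes phosphatidic acid, by 1.48, Cidea by 0.87 and the fatty acid transporter Cd36 by 0.59 (adjusted p = 4.11e-12, and adjusted p = 0.0458 with an estimated correlation). The target genes Fabp4, Lpl and Pck1 had values of 0.28, 0.26 and 0.31 that did not pass the test (adjusted p = 0.162, 0.0751 and 0.0957). Of 15 genes of glucose production, glycolysis and glycogen, 9 rose, with pyruvate carboxylase (Pc) at 1.42 and Ugp2 at 0.91 (adjusted p = 2.29e-06, and adjusted p = 0.0458 with an estimated correlation). The brown-fat-associated list had 6 measured members, of which Fabp3, Cpt1b and Cidea rose (adjusted p = 2.76e-06, and adjusted p = 0.00831 with an estimated correlation). The joint fit of all tissues held 12 members of this list. Cpt1b and Cidea are also counted in the lists above, so this result is not independent of theirs. Of 15 genes of triglyceride synthesis and lipolysis, 9 rose, such as Lpin1 by 0.95 and Dgat1 by 0.80, and the lipolysis inhibitor G0s2 fell by 0.50 (adjusted p = 2.29e-06, and adjusted p = 0.167 with an estimated correlation). Of 11 adipocyte markers, Aqp7, Cfd and Lipe rose and Lep fell (adjusted p = 0.00472, and adjusted p = 0.211 with an estimated correlation), a call that quantile normalization also ended. Of 17 fatty acid synthesis genes, 6 rose, such as Elovl6 by 0.95 and Pgd by 0.83, and the desaturase Fads1 fell by 1.03 (adjusted p = 6.72e-05, and adjusted p = 0.177 with an estimated correlation).

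Macrophage, antigen presentation and cell cycle lists were lower in the same comparison. Of 21 macrophage markers, 10 fell and 0 rose, with Spp1 at -2.19, Gpnmb at -1.15, Cd53 at -0.97 and Cd68 at -0.85 (adjusted p = 3.82e-05, and adjusted p = 0.177 with an estimated correlation). Of 14 genes of antigen presentation and lymphocytes, 8 fell, such as Coro1a by 1.18, Cd37 by 1.03 and Cd74 by 0.85 (adjusted p = 0.000634, and adjusted p = 0.211 with an estimated correlation). Of 19 cell cycle genes, 7 fell, with the tubulin regulator Stmn1 at -1.21, Ccnb2 at -1.15 and Cdk1 at -0.91 (adjusted p = 0.00145, and adjusted p = 0.0991 with an estimated correlation). Of 36 genes of the extracellular matrix and fibroblasts, 9 fell, including Col14a1 by 1.01, Tgfb1 by 0.98 and Lum by 0.80, and 3 rose, Postn by 1.40, Col6a3 by 0.79 and Col4a1 by 0.45 (adjusted p = 0.782 for the list). Pde3b, which breaks down cyclic AMP in response to insulin, rose by 1.21 and the stress gene Gadd45a fell by 1.07. Leptin fell by 0.81 ± 0.26 (adjusted p = 0.0315), a call that ended without any 1 of the 3 untreated obese arrays or with no filter, with adjusted p up to 0.132. Pparg had a value of 0.07 ± 0.12 (adjusted p = 0.717). In total 858 probe sets were higher and 1105 lower (limma), 1040 of them without overlap between the 12 ligand arrays and the 3 untreated arrays. Of all tested probe sets 11.6% had no overlap, where chance gives 0.440%. Centring each array on its median gave 1145 higher and 660 lower, and for troglitazone it moved the median of all probe sets by 0.14. Without untreated obese replicate 1 the total was 1184.

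**Figure D1:**
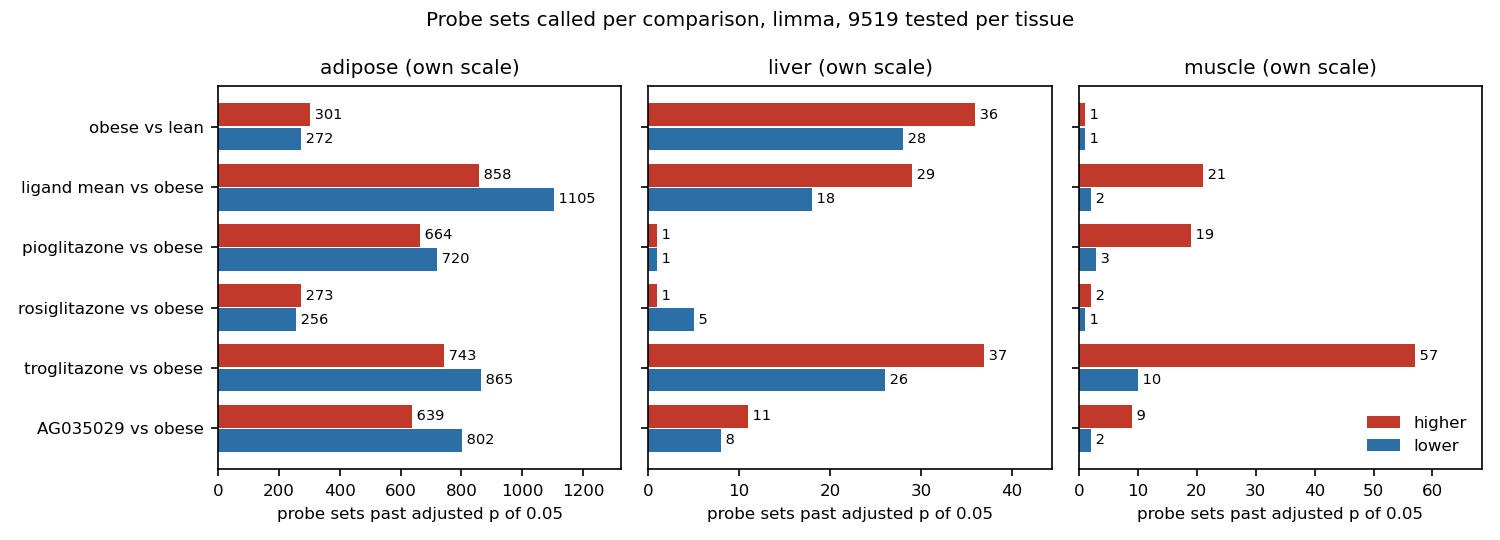
Probe sets past an adjusted p of 0.05 in each tissue (limma, 9519 tested per tissue, each panel on its own scale), higher in red and lower in blue, for obese against lean rats, the mean of the ligands and each ligand against untreated obese rats. The ligand mean had 858 higher and 1105 lower probe sets in adipose tissue, 29 and 18 in liver, and 21 and 2 in muscle.

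Each ligand was also compared with untreated obese adipose tissue. Fabp3 rose by 5.02 with pioglitazone, 4.89 with rosiglitazone, 4.87 with troglitazone and 4.48 with AG035029, and Cyp1b1 fell, with changes of -2.72, -2.30, -3.29 and -2.88 in the same order. The fatty acid oxidation list had 22, 16, 20 and 20 of its 24 members higher, with list medians of 1.08, 0.82, 1.11 and 0.92 (adjusted p = 0.0078, 0.00781, 0.00806 and 0.0108 with an estimated correlation). Macrophage markers fell for 9, 1, 11 and 11 of 21 members, and Spp1 had values of -2.47, -0.77, -2.84 and -2.67, of which that of rosiglitazone did not pass the test (adjusted p = 0.588). The 3 rosiglitazone arrays had Spp1 signals of 1445, 4876 and 234, and the change was -0.90, -1.77 and 0.36 without replicates 1, 2 and 3 (adjusted p = 0.636, 0.06 and 0.797). Macrophage markers that fell with rosiglitazone then numbered 1, 1 and 0. The calls numbered 664 higher and 720 lower for pioglitazone, 273 and 256 for rosiglitazone, 743 and 865 for troglitazone, and 639 and 802 for AG035029. Median centring gave 810 and 438 for pioglitazone, 294 and 144 for rosiglitazone, 1098 and 432 for troglitazone, and 627 and 600 for AG035029. Without untreated obese replicate 1 the totals were 824 for pioglitazone, 318 for rosiglitazone and 913 for AG035029. The pioglitazone total was 852 without its replicate 1, and the AG035029 total was 917 without its replicate 2. The rosiglitazone total was 351 and 286 without untreated obese replicates 2 and 3, and 318 and 235 without its own replicates 1 and 3. It was 790 without its replicate 2, and 865 when that array and the other arrays in doubt were left out.

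The 4 ligands moved many of the same adipose genes. Of 2277 probe sets called for any ligand, 431 were called for all 4 and 1 was called in opposite directions, against 0.0998 higher and 0.148 lower for independent lists. Simulated data with the same shared controls and no ligand effect gave a mean of 0 for all 4. They had a mean of only 0.3 called for any ligand, so that value follows by construction. The mean covariance of the fold changes between ligands was 0.134, against 0.0186 in the simulated data. All comparisons share the same 3 untreated arrays, which cannot be split into 2 sets of at least 2, so part of the excess may come from them. Tests of the differences among ligands called 3 probe sets (limma F-test), and 878 had an unadjusted p under 0.05. Tissue factor (F3), the trigger of coagulation, was lower with rosiglitazone than with AG035029 by 0.94 in log2 (95% interval -1.17 to -0.72), and the actin-binding gene Cotl1 was 1.67 higher (95% interval 1.23 to 2.12). The myeloid receptor gene Cd300c2 was 0.93 higher in the same difference (95% interval 0.61 to 1.25, adjusted p = 0.023), a call that ended in 2 alternatives and without AG035029 replicate 1 or 3 or rosiglitazone replicate 1 or 3, with adjusted p up to 0.167. An unnamed probe set was lower with pioglitazone, rosiglitazone and troglitazone than with AG035029, by values of -2.59, -2.42 and -2.28. The F-tests of F3 and Cotl1 did not pass in a fit of the 12 ligand arrays alone or with arrays in doubt left out, with adjusted p up to 0.0761 and 0.0978. The test of Cotl1 also ended with array weights and without AG035029 replicate 3 or rosiglitazone replicate 1. That of the unnamed probe set ended without AG035029 replicate 2 or 3, with adjusted p up to 0.0706. The number of probe sets called by the F-test was 1 without AG035029 replicate 3, and 5 without rosiglitazone replicate 3 or troglitazone replicate 1. No probe set differed between pioglitazone and rosiglitazone, pioglitazone and troglitazone, or rosiglitazone and troglitazone (limma, counts of 0), where 581, 666 and 917 had an unadjusted p under 0.05. The median 95% interval of a difference between ligands reached 0.34 to each side in adipose tissue, 0.55 in liver and 0.52 in muscle, so missing the threshold does not show that ligands act alike.

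A further question was whether the ligands moved obesity-changed genes back towards the lean level. In adipose tissue 172 of the 573 obesity-changed probe sets moved back and 83 moved further away. Of the 301 higher in obese rats 118 fell, against 34.9 for independent lists, and of the 272 lower 54 rose, against 24.5. Of those that moved further, 48 rose, against 27.1 for independent lists, and 35 fell, against 31.6. Both comparisons use the same untreated obese arrays with opposite signs. That alone favours moves back over moves further, so independent lists are not a fair reference here. Genes that moved back included Spp1, Gpnmb, Gatm, Atp1b1, Cd68 and Klf15, and Alb, Agpat2 and Ehhadh went beyond their lean levels. Fabp3, Cidea, Cyp4b1, Bdh1, Elovl6 and Me1, all higher in obese rats, rose further. Simulated data with the same shared controls and no ligand effect gave a mean of 0.01 probe sets moved back, a count near 0 by construction. The correlation across probe sets between the obesity and ligand changes was -0.179, against -0.306 in the simulated data, and the covariance was -0.0234 against -0.0186. The correlation was thus weaker, and the covariance only slightly stronger, than the shared arrays alone give. How far the moves back exceed the effect of the shared arrays is therefore not settled. Without untreated obese replicates 1, 2 and 3 the number moved back was 114, 114 and 100, and with array weights it was 329.

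**Figure D2:**
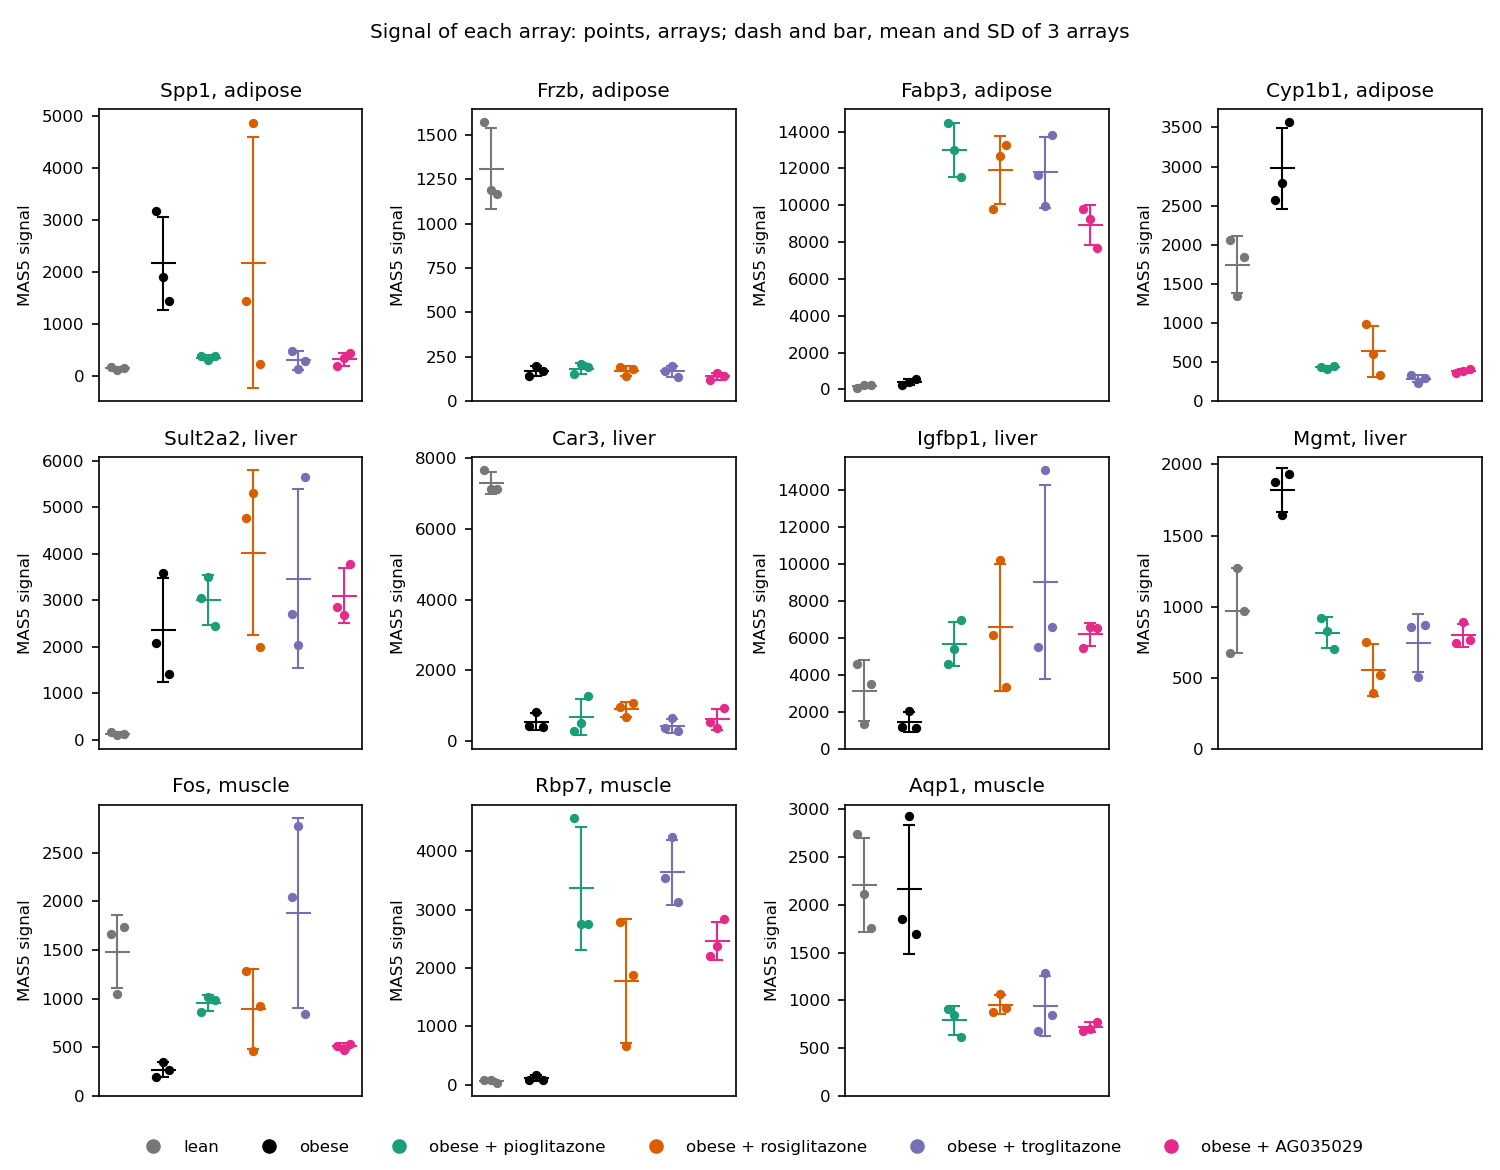
Signals of single arrays (points) with the mean and SD of 3 arrays for genes named in the text, by tissue and group. Fabp3 in adipose tissue had a mean of 405 in untreated obese rats and Rbp7 in muscle a mean of 114, and both genes rose under the ligands by over 4 on the log2 scale.

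In liver, obese rats had more transcript of several lipid-making enzymes than lean rats. The stearoyl-CoA desaturase Scd rose by 3.38 ± 0.50 in log2, from a mean signal of 2770 to 26906 (adjusted p = 0.000729), the glycolytic enzyme Pklr by 3.32 ± 0.48, the fatty acid synthase Fasn by 2.25 ± 0.41 and the fatty acid elongase Elovl6 by 1.85 ± 0.32. The sulfotransferases Sult2a2 and Sult2a6 rose by 3.91 ± 0.37 and 1.93 ± 0.32, and the phosphatase gene Ptprs by 2.76 ± 0.37, although its other probe set had a value of 0.06. Carbonic anhydrase Car3 fell by 3.76 ± 0.42, the sulfotransferases Sult1c2a and Sult1c3 by 3.58 ± 0.53 and 2.86 ± 0.37, the cytochromes Cyp3a2 and Cyp3a18 by 2.99 ± 0.53 and 2.27 ± 0.30 and the cadherin Cdh17 by 2.94 ± 0.36. Of 18 fatty acid synthesis genes, 6 rose and 0 fell, and 14 rose when adjusted over the list alone, with Me1 at 1.59 and Acaca at 1.34 (list median 0.86, adjusted p = 2.64e-17, and adjusted p = 0.0776 with an estimated correlation). Other probe sets of Fasn and Me1 had values of 1.33 and 0.42 that did not pass (limma, adjusted p = 0.178 and 0.744). Of 17 cholesterol synthesis genes, Idi1 and Sqle fell, with changes of -2.14 and -2.61, and 4 fell when adjusted over the list alone (adjusted p = 0.000161, and adjusted p = 0.337 with an estimated correlation). Of 17 genes of endoplasmic reticulum stress, Xbp1 fell by 1.18, and 5 fell when adjusted over the list alone (adjusted p = 6.31e-05, and adjusted p = 0.0776 with an estimated correlation). Of 30 genes of bile acid and xenobiotic metabolism, Cyp3a18 and Cyp3a2 fell and Aldh1a1 rose by 1.38 (adjusted p = 0.476 for the list). The clock gene Per1 fell by 1.52 and the lipolysis inhibitor G0s2 rose by 1.27. Altogether 36 probe sets were higher and 28 lower (limma), and all 64 lacked overlap between groups. Of all tested probe sets 13.7% had no overlap, where chance gives 10%. The calls of Sqle, Per1, G0s2, Me1 and the lower Pklr probe set each ended in several alternatives, with adjusted p up to 0.224, and that of Fasn without lean replicate 2 (adjusted p = 0.0645).

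In liver under the ligands, the insulin-repressed gene Igfbp1 rose by 2.20 ± 0.33 in log2 (adjusted p = 0.00314) and the insulin receptor substrate Irs2 by 1.70 ± 0.33. The flavin monooxygenase Fmo1, lower in obese than in lean rats by 1.56, rose by 1.48 ± 0.15 (adjusted p = 2.14e-05), the glutamate transporter Slc1a2 rose by 1.98 ± 0.34, the RNA editing enzyme Adarb1 by 1.96 ± 0.42 and the methyltransferase Inmt by 1.65 ± 0.37. Another probe set of Adarb1 had a value of -0.15 (adjusted p = 0.935). The DNA repair gene Mgmt fell by 1.34 ± 0.20, Cavin3 by 1.26 ± 0.20, Tsc22d1 by 1.21 ± 0.21, the growth factor binding gene Igfals by 1.07 ± 0.22, the fatty acid elongase Elovl5 by 1.001 ± 0.16 and the apolipoprotein Apoa4 by 0.96 ± 0.16. Of 18 fatty acid synthesis genes, Elovl5 and Pklr fell and 8 fell when adjusted over the list alone, while Scd had a value of -1.47 that did not pass (list median -0.54, adjusted p = 1.97e-10, and adjusted p = 0.215 with an estimated correlation). Of 30 genes of bile acid and xenobiotic metabolism, the cytochrome reductase Por rose by 1.22, Cyp3a18 by 1.04 and Cyp1a2 by 0.84, and 9 rose when adjusted over the list alone (adjusted p = 1.42e-05, and adjusted p = 0.095 with an estimated correlation). Per1 rose by 1.41 and the glycogen phosphorylase Pygl fell by 0.87. Of 54 genes of the citrate cycle and oxidative phosphorylation, 0 passed (limma, list median -0.15), while the list test gave adjusted p = 0.00138 and adjusted p = 0.27 with an estimated correlation. Among PPARgamma target genes, 0 of 22 passed, and Pparg had a value of -0.52 ± 0.25 (adjusted p = 0.458).

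Counts in liver were small and moved with single arrays. The ligand mean had 29 probe sets higher and 18 lower (limma), and 27 of these did not overlap. Of all tested probe sets 1.48% had no overlap, where chance gives 0.440%. The total was 21, 90 and 18 without untreated obese replicates 1, 2 and 3, and 72 without rosiglitazone replicate 1. It was 29 with no filter, 28 with no trend and 23 with arrays in doubt left out. In liver these were untreated obese replicate 3 and rosiglitazone replicate 2, with log2 actin 3'/5' ratios of 1.82 and 1.71 against a tissue median of 0.959. The calls of Irs2, Inmt, Tsc22d1, Igfals, Pklr, Pygl, Por, Cyp1a2 and Cyp3a18 ended with arrays in doubt left out, with adjusted p over all alternatives up to 0.33, and those of Slc1a2 and Cavin3 without untreated obese replicate 1 (adjusted p = 0.0745 and 0.0522), of Apoa4 without untreated obese replicate 3 (adjusted p = 0.0503), of Per1 without untreated obese replicate 1 or 2 (adjusted p up to 0.138) and of Adarb1 with no filter, the replicate block or a pseudocount of 80. Single ligands had 1 higher and 1 lower (pioglitazone), 1 and 5 (rosiglitazone), 37 and 26 (troglitazone) and 11 and 8 (AG035029). The troglitazone total was 34, 96 and 20 without untreated obese replicates 1, 2 and 3, and 23 and 26 without its own replicates 2 and 3. The AG035029 total was 35 without untreated obese replicate 2, and 9, 10 and 12 without its own replicates 1, 2 and 3. The pioglitazone total was 5, 13 and 0 without untreated obese replicates 1, 2 and 3, and 0 without its own replicate 2. The rosiglitazone total was 22 and 0 without untreated obese replicates 2 and 3, and 50, 0 and 19 without its own replicates 1, 2 and 3. With troglitazone 6 of 30 genes of bile acid and xenobiotic metabolism rose (list median 0.41, adjusted p = 4.66e-10, and adjusted p = 0.0202 with an estimated correlation), and 3 of 17 cholesterol synthesis genes rose (adjusted p = 4.33e-08, and adjusted p = 0.16 with an estimated correlation). Fmo1 alone was called for all 4 ligands, out of 74 probe sets called for any, where independent lists give 4.72e-10. The covariance between ligands was 0.0900, against 0.0498 in simulated data with shared controls. Obp3, which encodes an odorant-binding urinary protein, was the single probe set of the F-test among ligands (adjusted p = 0.0337), with mean signals of 2748 under rosiglitazone, 407 under pioglitazone, 539 under troglitazone and 241 under AG035029, and 601 had an unadjusted p under 0.05. That call was lost in a fit of the ligand arrays alone, with no filter, no trend, array weights or arrays in doubt left out, and without AG035029 replicate 1 or 2, pioglitazone replicate 2, rosiglitazone replicate 2 or 3, or troglitazone replicate 1, with adjusted p up to 0.428. In the differences between single ligands, the cyclin gene Ccnd3 was 1.59 higher with rosiglitazone than with AG035029 (95% interval 1.02 to 2.16, adjusted p = 0.046), and an unnamed probe set was 1.96 higher with rosiglitazone than with troglitazone (standard error 0.31, adjusted p = 0.0311). Both calls ended in at least 4 alternatives, that of Ccnd3 without AG035029 or rosiglitazone replicate 2 or 3 and that of the unnamed probe set without any 1 of the 6 arrays, with adjusted p up to 0.268 and 0.781. Of the 64 obesity-changed probe sets, 8 moved back, Cyp3a18, Nat8, Fmo1, Per1, Pklr, Apoa4, Camlg and an unnamed probe set, and Obp3 fell further. The Pklr probe set that moved back is the one that rose by 1.41 in obese rats. The Pklr probe set that rose by 3.32 had a ligand value of -1.14 that did not pass (limma, adjusted p = 0.236). Simulated data without a ligand effect gave a mean of 0.04 moved back, a count near 0 by construction. The covariance of the obesity and ligand changes was -0.0631 against -0.0497 in those data. Without 1 array the number moved back ran from 3 without lean replicate 2 to 14 without untreated obese replicate 2.

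In muscle, obese and lean rats differed at 2 probe sets (limma), and 464 had an unadjusted p under 0.05 where 476 were expected by chance. The total was 0, 4 and 0 without untreated obese replicates 1, 2 and 3, and 1 and 0 without lean replicates 2 and 3. The immediate early gene Fos fell by 2.36 ± 0.36 in log2 in obese rats (adjusted p = 0.0194), although its other probe set had a value of 0.34, and the higher probe set carries no symbol. The call of Fos ended without untreated obese replicate 1 or 3, without lean replicate 1 or 3, with no trend and with arrays in doubt left out, with adjusted p up to 0.147. Pparg had a value of -2.21 ± 0.40 that did not pass (adjusted p = 0.0837), with mean signals of 274 in lean and 43.6 in obese rats, the latter under 50. Of 16 immediate early and heat shock genes 1 fell, and Egr2 and Ier2 had values of -1.28 and -1.25 that did not pass (list median -0.49, adjusted p = 5.64e-06, and adjusted p = 0.211 with an estimated correlation). Of 18 genes of muscle atrophy and glucocorticoid response 0 passed (limma), with Fkbp5 at 1.05 (list median 0.37, adjusted p = 1e-05, and adjusted p = 0.211 with an estimated correlation).

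Under the ligands, muscle samples gained transcripts that are typical of fat cells and lipid synthesis. The retinol-binding gene Rbp7 rose by 4.34 ± 0.31 in log2 (adjusted p = 1.04e-07), the lipogenic regulator Thrsp by 3.49 ± 0.46, Scd by 3.15 ± 0.43, the glyceroneogenic enzyme Pck1 by 2.69 ± 0.43, the detoxifying enzyme Mgst1 by 2.68 ± 0.48 and the fatty acid carriers Fabp4 and Fabp5 by 2.03 ± 0.26 and 1.58 ± 0.18. Pparg rose by 2.01 ± 0.32 (adjusted p = 0.00278), the monoglyceride lipase Mgll by 1.90 ± 0.27, the glycerol channel Aqp7 by 1.71 ± 0.29 and the sterol-responsive gene Insig1 by 1.39 ± 0.27. The water channel Aqp1 fell by 1.31 ± 0.18 and the growth factor binding gene Igfbp5 by 0.89 ± 0.12, with a value of 0.29 at another Igfbp5 probe set. Another Aqp1 probe set had a value of -0.73 that did not pass (limma, adjusted p = 0.213). Fos rose by 1.70 ± 0.28, and its other probe set had a value of -0.41.

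Of 23 PPARgamma target genes in muscle, 5 rose and 0 fell, and 11 rose when adjusted over the list alone (list median 0.66, adjusted p = 1.06e-25, and adjusted p = 0.00526 with an estimated correlation). Of 8 adipocyte markers Fabp4, Pparg and Aqp7 rose, while the adipocyte protease gene Cfd had a value of 0.97 (list median 0.86, adjusted p = 3.96e-14, and adjusted p = 0.00526 with an estimated correlation). Of 13 genes of triglyceride synthesis and lipolysis, Pck1, Mgll and Aqp7 rose, and 6 rose when adjusted over the list alone (adjusted p = 4.05e-14, and adjusted p = 0.0128 with an estimated correlation). Of 17 fatty acid synthesis genes, Scd and Thrsp rose and 10 rose when adjusted over the list alone (adjusted p = 6.11e-14, and adjusted p = 0.063 with an estimated correlation). Of 7 adipokine genes 0 passed (limma), and 2 rose when adjusted over the list alone (adjusted p = 0.00346, and adjusted p = 0.0444 with an estimated correlation). An excess over the mean of untreated obese muscle was taken for 20 adipose-enriched probe sets not called in muscle. It was given as a percent of the gap to untreated obese adipose tissue. Its median was -0.333 to 0.111% on untreated obese arrays, near 0 by construction, so it does not measure fat in untreated muscle. It was 10.1, 10.9 and 1.40% on troglitazone arrays and 6.42, 0.973 and 5.33% on pioglitazone arrays. It was 1.09 to 1.68% on rosiglitazone arrays, and -0.230, 3.57 and 0.473% on AG035029 arrays. On those AG035029 arrays Rbp7 had signals of 2205, 2370 and 2832, Thrsp of 778, 5244 and 2078 and Cfd of 287, 1997 and 748. Untreated obese arrays had 83.3 to 172 for Rbp7, 327 to 552 for Thrsp and 439 to 617 for Cfd. Slow-fibre genes varied widely within groups, and Myh7 ran from 2280 to 33285 among the 3 untreated obese arrays. Of 15 slow muscle fibre genes 0 passed (limma, list median 0.62, adjusted p = 0.000787, and adjusted p = 0.424 with an estimated correlation), and the list mean was 0.57, and -0.17 without untreated obese replicate 1. Of 24 genes of mitochondrial fatty acid oxidation 0 passed (limma).

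**Figure D3:**
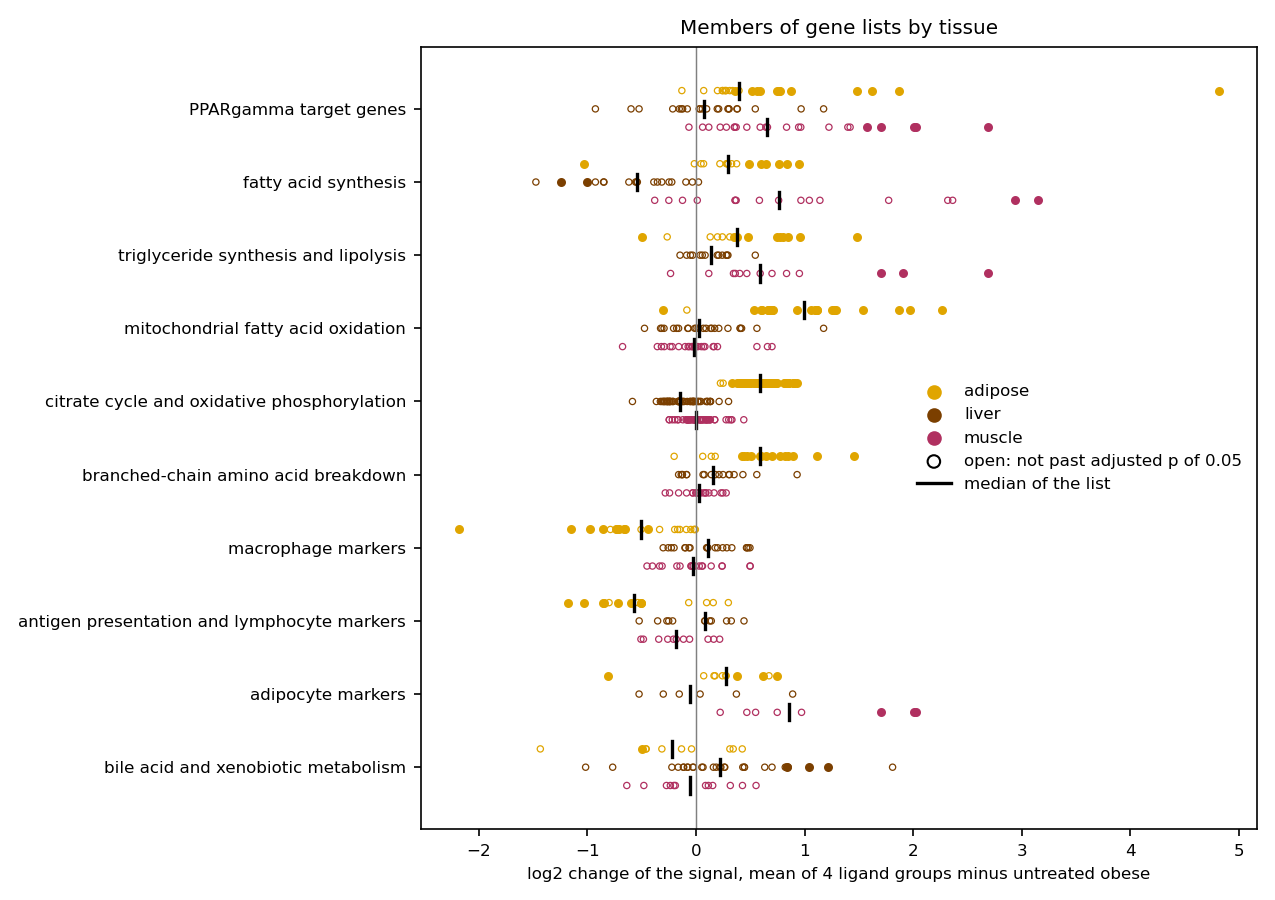
Log2 change of each measured member of gene lists, mean of the 4 ligand groups minus untreated obese rats, by tissue (filled points passed an adjusted p of 0.05, lines are list medians). The median of mitochondrial fatty acid oxidation was 0.996 in adipose tissue, and the median of adipocyte markers was 0.27 in adipose tissue and 0.86 in muscle.

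The ligand mean in muscle had 21 probe sets higher and 2 lower (limma), 22 of the 23 without overlap between arrays. Of all tested probe sets 0.704% had no overlap, where chance gives 0.440%. The total was 37 without untreated obese replicate 2 and 45 without troglitazone replicate 3. Without untreated obese replicate 1 the calls of Pck1, Aqp7 and Fos ended, with adjusted p = 0.0583, 0.0995 and 0.0826. The calls of Mgst1 and Insig1 ended without any 1 of the 3 untreated obese arrays and with no trend, with adjusted p up to 0.08 and 0.188. Single ligands had 19 higher and 3 lower (pioglitazone), 2 and 1 (rosiglitazone), 57 and 10 (troglitazone) and 9 and 2 (AG035029). Fits of only the arrays compared gave totals of 14 for rosiglitazone, 21 for troglitazone and 1 for AG035029. No trend gave 14 for pioglitazone, 33 for troglitazone and 2 for AG035029, and array weights gave 15 for rosiglitazone. The troglitazone total was 25 and 36 without untreated obese replicates 1 and 3, and 26 and 103 without its own replicates 2 and 3. The pioglitazone total was 13 and 11 without untreated obese replicates 1 and 3, and 8 and 10 without its own replicates 1 and 3. The AG035029 total was 3 and 5 without untreated obese replicates 1 and 3 and 3 without its own replicate 3, and the rosiglitazone total was 8 without untreated obese replicate 2. Rbp7 rose by 4.68 with pioglitazone, 3.59 with rosiglitazone, 4.83 with troglitazone and 4.27 with AG035029, and 2 of 72 probe sets called for any ligand were called for all 4, against 2.26e-08 for independent lists of higher probe sets. The covariance between ligands was 0.0715, against 0.0460 in simulated data with shared controls. The F-test among ligands called 0 probe sets (limma), 921 had an unadjusted p under 0.05, and it called 9 and 38 without troglitazone replicates 1 and 3, 2 and 3 without AG035029 replicates 1 and 2, 2 without pioglitazone replicate 1 and 1 without rosiglitazone replicate 3. Vimentin (Vim), an intermediate filament gene, was 1.06 lower in log2 with rosiglitazone than with troglitazone (95% interval -1.40 to -0.72, adjusted p = 0.0252). That call was lost with median centring, no trend, array weights or a fit of the compared arrays alone, and without rosiglitazone replicate 1 or 2 or troglitazone replicate 2, with adjusted p up to 0.427. Vim was also 0.97 higher with troglitazone than with AG035029 and the guidance gene Rgma was lower, with a difference of -1.59 (95% intervals 0.63 to 1.31 and -2.14 to -1.03, adjusted p = 0.0435 for both). For pioglitazone minus rosiglitazone, Ly6e had a difference of 1.47 and Ins1 of -1.71 (95% intervals 0.96 to 1.97 and -2.30 to -1.12, adjusted p = 0.0352 for both). The calls of Vim and Rgma ended in 7 alternatives and without troglitazone replicate 2 or AG035029 replicate 1 or 3, that of Rgma also without AG035029 replicate 2, with adjusted p up to 0.48. The calls of Ly6e and Ins1 ended in 6 and 7 alternatives and without any 1 of the 6 arrays, with adjusted p up to 0.303. Fos, 1 of the 2 obesity-changed probe sets, moved back, but the covariance of the obesity and ligand changes was -0.0350 against -0.0458 in simulated data with shared controls, so no reversal beyond the shared arrays was shown.

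**Figure D4:**
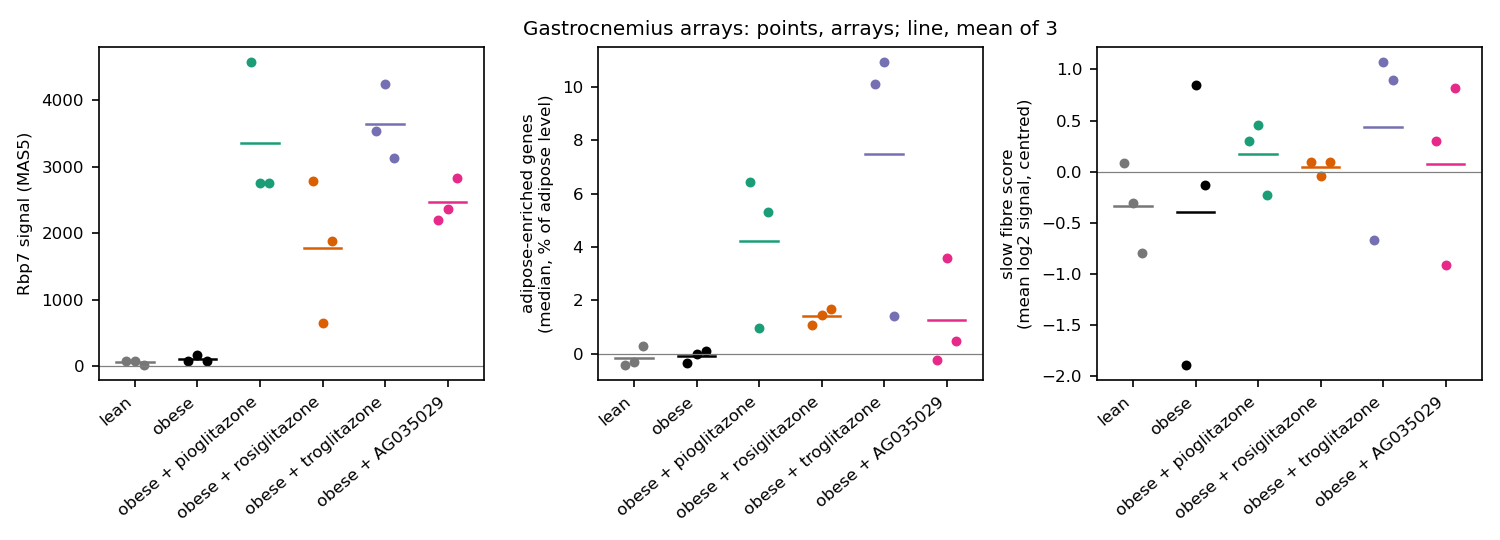
Slow-fibre score, median excess of adipose-enriched transcripts not called in muscle and Rbp7 signal on each gastrocnemius array (points) with group means (lines). The excess is over the mean of untreated obese muscle, as a percent of the gap to untreated obese adipose tissue. It reached 10.9% on 1 troglitazone array. Rbp7 lay between 83.3 and 172 on untreated obese arrays and between 660 and 4571 on ligand arrays.

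The tissue comparison asks whether the mean effect of the ligands differed between tissues. It did so at 568 of 11520 probe sets (limma F-test). Separate limma tests of each pair of tissues over the same 11520 probe sets were also made. They called 510 between adipose tissue and liver, 240 between adipose tissue and muscle and 99 between liver and muscle. Fabp3 changed by 4.82 in adipose tissue, -0.60 in liver and -0.07 in muscle, and Cyp1b1 by -2.80, 0.06 and -0.25. The peroxisomal hydrolase gene Nudt7 and the mitochondrial genes Etfdh and Acadl rose in adipose tissue by 1.66, 1.25 and 1.27 and lay between -0.31 and 0.12 in the other tissues, and Tmem176b fell by 1.34 in adipose tissue. Rbp7 rose by 1.32 in adipose tissue and 4.34 in muscle, against 0.22 in liver, and Thrsp rose by 3.49 in muscle against 0.27 in adipose tissue. The joint fit pools 1 spread per probe set over the tissues. Their median residual SDs were 0.25 in adipose tissue, 0.40 in liver and 0.39 in muscle. Joint calls within liver and muscle can therefore be too lenient. In this joint fit 12 probe sets were called in opposite directions in 2 tissues. These included Scd, at -1.47 in liver and 3.15 in muscle, and the cysteine metabolism gene Csad, at -0.84 and 0.81. In the fits per tissue 0 were opposite in liver and muscle (limma), since Scd did not pass in liver (adjusted p = 0.107) or Csad in muscle (adjusted p = 0.176). Dbi, Scp2 and the respiratory chain genes Ndufb1 and Ndufa2 rose in adipose tissue and fell in liver in the joint fit, and in the fit of liver alone they did not pass (adjusted p = 0.106, 0.154, 0.158 and 0.159). In the fits per tissue, Csad, Tsc22d1 and an unnamed probe set were called in opposite directions in adipose tissue and liver, with Csad at 0.45 and -0.84 and Tsc22d1 at 0.28 and -1.21. List tests between tissues were chosen after the results were seen. In them, mitochondrial fatty acid oxidation was 0.90 higher in adipose tissue than in liver and 0.95 higher than in muscle by median difference (adjusted p = 0.0017 and 0.000278 with an estimated correlation). Fatty acid synthesis was 1.37 lower in liver than in muscle (median difference -1.37, adjusted p = 0.00384 with an estimated correlation). In the fits per tissue, adipose tissue and muscle shared 7 higher probe sets, Aqp7, Gpihbp1, Insig1, Mgll, Mgst1, Rbp7 and Thrsp, where independent lists give 2.01. The shared Thrsp probe set is not the one above and rose by 0.52 in adipose tissue and 2.92 in muscle. Adipose tissue and liver shared 1 higher, against 1.89, and 1 lower, Mgmt, against 0.946. Liver and muscle shared 1 higher, Por, against 0.0356, and 0 lower (limma). Adipose tissue and muscle shared 2 lower, Aqp1 and Igfbp5, where independent lists give 0.217, and Pkp4 was called in opposite directions, at -0.49 in adipose tissue and 0.95 in muscle. Without untreated obese adipose replicate 1 the number of tissue differences was 369. The leptin receptor gene Lepr had 7 probe sets, of which 0 passed the signal filter in adipose tissue, and the 2 tested in liver and the 2 tested in muscle were not called in any comparison.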

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

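The tests of the 3 patterns below and the list tests between tissues were chosen only after the results were seen.

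The effect of the ligands differed between tissues, by a test of the difference itself, at 568 probe sets, and 12 probe sets were called in opposite directions in 2 tissues in the joint fit. Opposite calls in the fits per tissue, counted without a test of the difference, were 3 for adipose tissue and liver, 1 for adipose tissue and muscle and 0 for liver and muscle (limma). Of these, Tsc22d1 and Pkp4 are not among the 12. The F-test between tissues gave adjusted p = 6.41e-12 for Fabp3, with changes of 4.82 in adipose tissue, -0.60 in liver and -0.07 in muscle. It gave adjusted p = 9.91e-10 for 1 probe set of Alb, at 4.43, -0.28 and 0.89, and 6.09e-09 for the other, at 4.45, -0.17 and 0.10. For Cyp1b1 the adjusted p was 9.91e-10, with -2.80, 0.06 and -0.25. For Nudt7 it was 1.38e-08, with 1.66, 0.12 and -0.05. Rbp7 had adjusted p = 3.09e-08, with 1.32, 0.22 and 4.34. Etfdh had adjusted p = 1.2e-07, with 1.25, -0.31 and -0.16, and Acadl adjusted p = 1.44e-07, with 1.27, -0.29 and -0.24. Tmem176b had adjusted p = 3.72e-07, with -1.34, 0.33 and 0.02, and Thrsp adjusted p = 6.36e-07, with 0.27, -0.62 and 3.49. The list of fatty acid synthesis was 0.93 higher in adipose tissue than in liver by median difference (0.932, adjusted p = 7.32e-08), a call that was lost with adjusted p = 0.0833 with an estimated correlation. Its difference of liver minus muscle was -1.37 (-1.369, adjusted p = 1.49e-23, and adjusted p = 0.00384 with an estimated correlation). The citrate cycle and oxidative phosphorylation list was 0.74 higher in adipose tissue than in liver (0.743, adjusted p = 1.12e-45, and adjusted p = 0.00105 with an estimated correlation).

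Albumin mRNA rose in adipose tissue under the ligands. Liver RNA in the adipose samples is argued against, since the other 18 hepatocyte genes had a median excess of -0.000584% of their level in liver against 6.61% for albumin. At the share that albumin needs, all 18 would be abundant in adipose tissue, and 1 was, Rbp4, which adipose tissue itself expresses and which had the highest excess of 9.43%. A faulty probe set is argued against by the smaller of the changes of the 2 albumin probe sets, 4.43 (4.427). A response of adipose cells to the ligands may remain as a hypothesis, and the cell type that carries the transcript was not tested.

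Adipocyte and lipid genes rose in muscle under the ligands, and admixed fat cannot be told apart from a response of muscle. Over untreated obese muscle, the 21 probe sets that rose had a median excess of 16.1% of the gap to ligand-treated adipose tissue (7.22 to 97.3%). For 20 adipose-enriched probe sets that were not called in muscle the median was 2.37% and the highest 20.1%. That highest value belongs to a probe set of the fatty acid synthase Fasn, so the 20 include genes of lipid synthesis. The 21 were chosen for rising and the 20 for not being called, so a lower value for the 20 is partly built in. The profile of fat within muscle is not known from these arrays. Of the list of adipocyte markers, 8 genes were measured in muscle, and Fabp4, Aqp7 and Pparg also belong to the PPARgamma target list. More slow fibre tissue in the ligand samples is argued against, since the median change of the 21 probe sets was 1.88 (1.881) with a slow fibre score as covariate and 1.89 (1.885) without.

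Rosiglitazone had fewer calls in adipose tissue than the other ligands. Without its replicate 2, whose residual spread was 1.33 times the tissue median, it had 790 calls, where the other ligands had 852 to 1381 without 1 of their arrays, so this array may account for part of the gap. Degraded RNA on that array is argued against by its log2 actin 3'/5' ratio of 0.237, in a range from 0.0109 to 0.932. The mean position of its replicates 1 and 3 between untreated obese rats and the mean of the other ligands was 82.6% (76.4 and 88.9%). Single arrays of the other ligands lay from 80.1 to 103%, each placed against the ligands besides its own and rosiglitazone. The axes thus differ, and a smaller response stays open. Doses are not stated in the labels, and their effect was not tested.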

How the results depend on the processing

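All alternatives here were planned except the one that leaves out arrays in doubt, which was chosen after seeing the data. The cause was not tested for any change below unless stated. A stricter threshold lowers counts by construction.

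An adjusted p of 0.01 gave, in adipose tissue, 240 calls for obese against lean, 1110 for the ligand mean, 626 for pioglitazone, 192 for rosiglitazone, 829 for troglitazone, 672 for AG035029 and 76 probe sets moved back. In liver these were 36, 17, 0, 2, 15, 8 and 2, with 0 for differences among ligands. In muscle, obese against lean had 0, pioglitazone 11, troglitazone 22, AG035029 1 and moved back 0, and tissue differences numbered 259. With a pseudocount of 5, muscle differences among ligands numbered 2, and with a pseudocount of 80, liver probe sets moved back numbered 5. No filter gave 29 for the liver ligand mean, 0 for liver differences among ligands, 5 moved back in liver and 1 for muscle obese against lean. The filter at the 60th percentile gave 15 for liver rosiglitazone and 5 for muscle rosiglitazone. Quantile normalization gave 5 moved back in liver. Median centring gave 5 moved back in liver, 1 for muscle obese against lean and 5 for muscle rosiglitazone. No trend gave 28 for the liver ligand mean, 0 for liver pioglitazone, 2 for liver rosiglitazone, 19 for liver troglitazone and 3 moved back in liver. In muscle it gave 0 for obese against lean, 14 for pioglitazone, 33 for troglitazone, 2 for AG035029, 1 for differences among ligands and 0 moved back. Array weights gave 1106 for adipose obese against lean, 329 moved back in adipose tissue, 2 for liver rosiglitazone, 0 for liver differences among ligands, 5 moved back in liver and 15 for muscle rosiglitazone. The replicate block gave 2 for muscle differences among ligands. As a random block over tissues it had a consensus correlation of -0.0021. With arrays in doubt left out, adipose rosiglitazone had 865 and adipose differences among ligands 1. Liver then had 23 for the ligand mean, 0 for pioglitazone, 0 for rosiglitazone, 25 for troglitazone and 0 for differences among ligands, and muscle had 0 for obese against lean and 0 moved back. Fits of only the arrays compared gave 252 for adipose rosiglitazone and 1 for adipose differences among ligands. They gave 8 for liver pioglitazone, 0 for liver rosiglitazone, 34 for liver troglitazone, 0 for liver differences among ligands and 5 moved back in liver. In muscle they gave 4 for obese against lean, 14 for rosiglitazone, 21 for troglitazone and 1 for AG035029. With an estimated correlation 48 list tests were called, against 186.

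Leaving out 1 array gave, in adipose tissue, 319 to 433 calls for obese against lean, 1184 to 2255 for the ligand mean, 824 to 1073 for pioglitazone, 235 to 790 for rosiglitazone, 1134 to 1381 for troglitazone, 913 to 1313 for AG035029, 1 to 5 for differences among ligands and 100 to 217 moved back. In liver the ranges were 43 to 57, 18 to 90, 0 to 13, 0 to 50, 20 to 96, 9 to 35, 0 to 7 and 3 to 14. In muscle they were 0 to 4, 17 to 45, 8 to 22, 2 to 8, 25 to 103, 3 to 14, 0 to 38 and 0 to 3. Tissue differences ran from 369 to 629 and list tests from 169 to 196. Mean list changes turned direction in 4 cases. Without untreated obese muscle replicate 1, the ligand mean was -0.137 for fatty acid oxidation, -0.0919 for the citrate cycle list and -0.174 for slow fibre genes, and leaving out 1 array gave up to 0.155, 0.136 and 1.19. Without untreated obese muscle replicate 2, slow fibre genes were at -0.67 in obese against lean rats, and leaving out 1 array gave up to 0.696. Signal over background limits dim probe sets, and Pparg in untreated obese muscle had a mean of 43.6.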

Other observations

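Further members of the fixed lists moved in adipose tissue. In obese rats the insulin signalling genes Pik3r1 and Insr fell by 1.62 and 0.60, and the clock gene Per2 fell by 0.95. Under the ligands the insulin receptor substrate Irs3 rose by 0.89, the adaptor Sh2b2 by 1.21, and the receptor inhibitor Grb14 fell by 0.53, while the insulin signalling list as a whole had a median of 0.02 (adjusted p = 0.346). The glucocorticoid-responsive gene Fkbp5 rose by 0.94, the vascular growth factor receptor Kdr rose by 0.95, and the endothelial genes Emcn and Eng fell by 0.77 and 0.45. The adipokine Nampt rose by 0.89 and Angptl4 by 0.52. In liver under the ligands the binding protein Igfbp2 rose by 1.40 and the sterol reductase Tm7sf2 by 0.80. Calls of Igfbp2, Grb14, Eng, Per2, Insr and Pik3r1 each ended without at least 2 single arrays, with adjusted p up to 0.243.

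In muscle under the ligands, 16 lists passed with the fixed correlation and 4 with an estimated one. Those lost, besides fatty acid synthesis and slow fibre genes in the report, were brown-fat-associated genes (adjusted p = 0.00302, and adjusted p = 0.102 with an estimated correlation), peroxisomal genes (0.0237 and 0.103), inflammatory mediators (0.0165 and 0.101), hepatocyte markers (0.01 and 0.101), muscle atrophy genes (0.0113 and 0.223), fast muscle fibre genes (0.0209 and 0.555), genes of glucose production, glycolysis and glycogen (0.0378 and 0.332) and immediate early genes (3.81e-05 and 0.101). Lower lists were extracellular matrix (0.00429 and 0.306) and clock genes (0.0341 and 0.161).

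Other splits of the arrays were counted for each result. For the ligand mean, 1 of 100 drawn splits, the real one, gave as many calls in each tissue, so chance can be excluded, with 1963 against a highest other of 927 in adipose tissue, 47 against 13 in liver and 23 against 3 in muscle. For tissue differences only the real split gave as many (568 against 71). Its splits break up the ligand effect within each tissue, so they cannot separate a tissue difference from an effect that the tissues share. For probe sets moved back in adipose tissue only the real split gave as many (172 against 96). Those splits also break up the ligand effect itself, so they cannot separate a move back from ligand changes unrelated to obesity. For probe sets moved back in liver only the real split gave as many, but the margin is 1 (8 against 7), and leaving out 1 array gave as few as 3, so chance is not clearly excluded. For list tests only the real split gave as many, but the margin is 3 (186 against 183), and leaving out 1 array gave as few as 169, so chance is not clearly excluded. For differences among ligands in adipose tissue 4 of 100 splits gave as many, but the real count was 3 against a highest other of 10, and 1 without AG035029 replicate 3, so chance is not clearly excluded. A split with several times the real count may point to a structure of the arrays, which was not tested. Chance cannot be excluded for differences among ligands in liver (17 of 100 splits, 1 against 5) or for probe sets moved back in muscle (12 of 100, 1 against 2). For differences among ligands in muscle the real count was 0 (limma, 921 at an unadjusted p under 0.05) against a highest other of 17, so 100 of 100 splits gave as many by construction.

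With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real value and the highest other were 573 and 0 for adipose obese against lean, 1384 and 0 for pioglitazone, 529 and 86 for rosiglitazone, 1608 and 0 for troglitazone, and 1441 and 0 for AG035029. In liver they were 64 and 2, 2 and 0, 6 and 7, 63 and 1, and 19 and 1, in the same order. In muscle they were 2 and 2, 22 and 4, 3 and 1, 67 and 4, and 11 and 1. As many calls came from 1 of the 10 splits in each case, and from 2 for liver rosiglitazone and muscle obese against lean.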
